A study of Mus musculus with 6 samples.

How the data were processed

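RNA sequencing libraries of mouse palate at E14.5 were compared between 2 genotypes, with 3 libraries in each. Per the labels, the tissue was the future anterior hard palate of C57BL/6 embryos and RNA was extracted with a kit for small samples. Both genotypes carried 1 Shox2-Cre allele and a homozygous floxed Nkx2-5 gene. The control kept a wild-type Shox2 allele beside the Cre allele, and the mutant had a null allele in its place. The control was therefore not wild type, although its libraries are titled so. Groups and replicate numbers were taken from the titles and genotype labels. The labels do not say whether a library came from 1 embryo or from several pooled embryos.

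The deposited files hold whole-number read counts per gene symbol, 1 file per library and 23420 genes in each. HISAT2 and StringTie, and both the mm9 and the mm10 genome builds, are named per the submitters' processing notes, without versions. HISAT2 is also named in 4 of the 6 files, per the file headers. The read counter, its strand setting and the gene annotation are not given in the sources used here, so genes that overlap on opposite strands cannot be told apart.

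The deposited counts of low genes were mostly even numbers, as when both mates of a pair are counted one by one. Among counts from 5 to 50, even values made up 63.6%, 64.1% and 64.5% in control replicates 1, 2 and 3. The shares were 99.7%, 73.0% and 65.9% in mutant replicates 1, 2 and 3. How mutant replicate 1 came to differ from the other 5 libraries in this is not given in the sources used here. Counts that come in pairs are not independent reads, so intervals and floors that rest on counts cover counting error only and are too narrow.

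Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, libraries were scaled with TMM, and the quasi-likelihood F test compared mutant with control without a covariate. The Benjamini-Hochberg adjusted p threshold was 0.05. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM, given as mean and SD over 3 libraries. Where all libraries of a group had no counts, the fold was bounded with a floor of 3 counts over the group.

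The genes to name were set by rule before the data were examined. They were Shox2 and Nkx2-5, then the 10 largest rises and 10 largest falls by log2 fold change. These had to pass the adjusted p threshold, have an average log2 CPM of at least 1 and have groups that did not overlap. Shox2, sex-linked genes, predicted genes and pseudogenes were left out of those 20. For each gene list, up to 4 called members with the smallest p followed, or 2 members as values where none was called. Some genes that the rule names are not reported here. Other genes named in the text were chosen after their values were seen, and the text says so.

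The 30 gene lists were also fixed before the data were examined. They cover osteoblasts, chondrocytes, anterior palate, posterior palate, palatal mesenchyme factors, tendon, a sinoatrial program and Hox genes. Pathway and process lists cover BMP and activin, WNT, hedgehog, FGF, retinoic acid, Notch, proliferation, p53 targets and apoptosis, and hyaluronan and matrix. Cell type lists cover epithelium, nasal and olfactory cells, tooth germ epithelium, skeletal muscle, endothelium, red blood cells, macrophages, osteoclasts, nerve and glia, and mural cells. The last 3 lists hold stress and immediate early genes, mitochondrial transcripts, and sex-linked genes. No mitochondrial transcript was among the genes of the files, so 29 lists were tested. Another 5 lists were added after the data were seen: motile cilium families, small proline-rich genes, ribosomal protein genes, embryonic age genes and lung genes.

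Lists were tested with camera of limma 3.58.1, two-sided, with a preset correlation of 0.01 between genes, on log2 CPM with a prior count of 2. Adjusted p covers the 29 lists, and the 5 added lists were adjusted on their own. Camera with an estimated correlation and fry were run beside it. Counts of called members are given over all tested genes and adjusted over the list alone. Symbols were matched to GENCODE M21 on GRCm38 for gene positions, GC content and length, with 23267 of 23420 symbols matched (99.3%). For 5 list members an older symbol was used in the files.

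The edgeR and camera steps were tested on simulated data with known answers. Counts of 16604 genes were drawn with the measured means, library sizes and gene-wise dispersions, with 200 genes changed, in 10 draws. The mutant against control test recovered 24.3% of genes changed 1.5-fold, 61.6% at 2-fold and 82.1% at 4-fold. Unchanged genes made up 7.7% of the calls on average (2.6% to 13.6% over the draws), above the nominal 5% for the adjusted p. Among unchanged genes 4.7% had an unadjusted p under 0.05. In the data 7606 genes were called, far more than the 200 changed here, so these shares need not hold for the real comparison. Simulated genes were drawn independently of each other, so the preset correlation of camera was not tested.

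Alternatives fixed beforehand were other normalizations, other filters, DESeq2 1.42.0, limma-voom, each library left out, the replicate number as a block, globin genes left out, and a 1.5-fold threshold. Alternatives added after the data were seen were thinning to the smallest library, halved counts, X and Y genes left out, and a Y-linked covariate. Correction for GC content and length, as fitted and centred, and leaving out replicate 1 of both groups were also added then.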

Results

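The palatal tissue that forms the anterior hard palate was profiled by RNA sequencing at E14.5 in control embryos and in embryos lacking Shox2, a homeobox transcription factor of the anterior palate. The comparison addresses what Shox2 deficiency changes in the tissue that gives rise to the bony palatine process of the maxilla. Each group had 3 libraries, and p-values measure the spread between these libraries, since the labels do not say how many embryos each holds. Total counts were 81950407, 105125474 and 134813429 in control replicates 1, 2 and 3 and 53331397, 52668242 and 53049171 in the mutants. Every control was thus deeper than every mutant, and depth and genotype coincide. Pairs of libraries within a group correlated at 0.975 to 0.992 and pairs between groups at 0.894 to 0.934, across genes. No pair of libraries within a group agreed within sampling noise, with chi-square per degree of freedom from 15.6 to 138.2. The first principal component, with 78.4% of the variance, separated the genotypes. The second, with 8.4%, set mutant replicate 1 (52.27) apart from mutant replicates 2 and 3 (-22.58 and -23.4). Control replicate 1 also stood apart from its group. Of 14488 genes, 355 lay over 2-fold below the other 2 controls in control replicate 1. In mutant replicate 1, 340 lay over 2-fold below the other 2 mutants.

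Shox2 was low in every mutant library. Its level was 88.2, 68.2 and 81.7 CPM (counts scaled to library size) in control replicates 1, 2 and 3 and 5.3, 4.12 and 3.13 CPM in the mutants. The mean fell from 79.3 ± 10.2 to 4.19 ± 1.09 CPM (SD, n = 3 each), a log2 fold change of -4.24 (SE 0.21, edgeR adjusted p = 0.000137). Shox2 lies on chromosome 3 from 66971727 to 66981771, minus strand, in GENCODE M21 on GRCm38. Nkx2-5, floxed in both genotypes, had 8, 0 and 4 counts in the controls and 0 in each mutant, too few to be tested.

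Of 16604 genes tested, 7606 were called by edgeR, 3999 higher and 3607 lower in the mutant. Changes over 2-fold were mostly rises, with 2306 genes higher and 563 lower. The groups did not overlap for 9781 tested genes (58.9%), where chance gives 10%. The biological coefficient of variation was 19.8%. Against a 1.5-fold threshold, 2472 genes were called, 1967 higher and 505 lower. Correcting for GC content and length without recentring moved the median of all genes by -0.236 on the log2 scale and the split to 2991 higher and 6243 lower. With the correction centred it was 4252 higher and 3613 lower. Without replicate 1 of both groups, 9104 genes were called.

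Genes of differentiated epithelium and of motile cilia were among the 10 largest rises. Krt13, a keratin of stratified oral epithelium, rose from 5.37 ± 2.52 to 957 ± 623 CPM (log2 fold change 7.47, SE 0.74). Cnfn, a cornified envelope gene, rose by 8.07 (SE 1.42), with 1.13, 20.5 and 46.5 CPM in the mutants. Sntn, a protein of the ciliary tip, rose by 8.31 (SE 0.88), and Cdhr3, a cadherin of ciliated airway cells, by 7.66 (SE 0.57). Sftpc, the surfactant protein C gene, rose by 9.18 (SE 0.73), from 4 counts over the controls to 8.36 ± 4.39 CPM. Tctex1d4 (8.02), Spata18 (7.64), Nhlrc4 (7.3), AU040972 (6.85) and Ocm (6.85) completed the 10. Adjusted p from edgeR for these 10 lay between 0.000234 for Cdhr3 and 0.00363 for Cnfn. Cnfn was not called by limma-voom (adjusted p = 0.133) or with the Y-linked covariate (adjusted p = 0.0671).

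Genes of bone matrix and of tooth signalling were among the largest falls. Fgf3, a growth factor of the tooth signalling centre, fell from 4.84 ± 1.34 to 0.0245 ± 0.0212 CPM (log2 fold change -7.53, SE 0.57). Ibsp, bone sialoprotein, fell from 1310 ± 898 to 28.9 ± 27.5 CPM (-5.51, SE 1.08). Dmp1, an osteocyte matrix gene (-5.32, SE 1.17), and Col22a1, a collagen of tissue junctions (-5.14, SE 0.79), fell. Dkk1, a secreted WNT antagonist, fell from 37.8 ± 18.8 to 1.01 ± 0.283 CPM (-5.23, SE 0.5). Stmn3 (-6.35) and the neuropeptide gene Vip (-5.96) also fell. Hbb-y, an embryonic beta globin, fell by 5.19 on the log2 scale. Dlx1as fell by 7.02, but it lies antisense to Dlx1 and its reads may not be separable without strand. Adjusted p from edgeR for these genes lay between 0.000189 for Dlx1as and 0.0088 for Dmp1. Dmp1 (adjusted p = 0.231) and Vip (adjusted p = 0.0732) were not called by limma-voom. With the Y-linked covariate Ibsp (adjusted p = 0.0558) and Dmp1 (0.216) were not called.

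**Figure D1:**
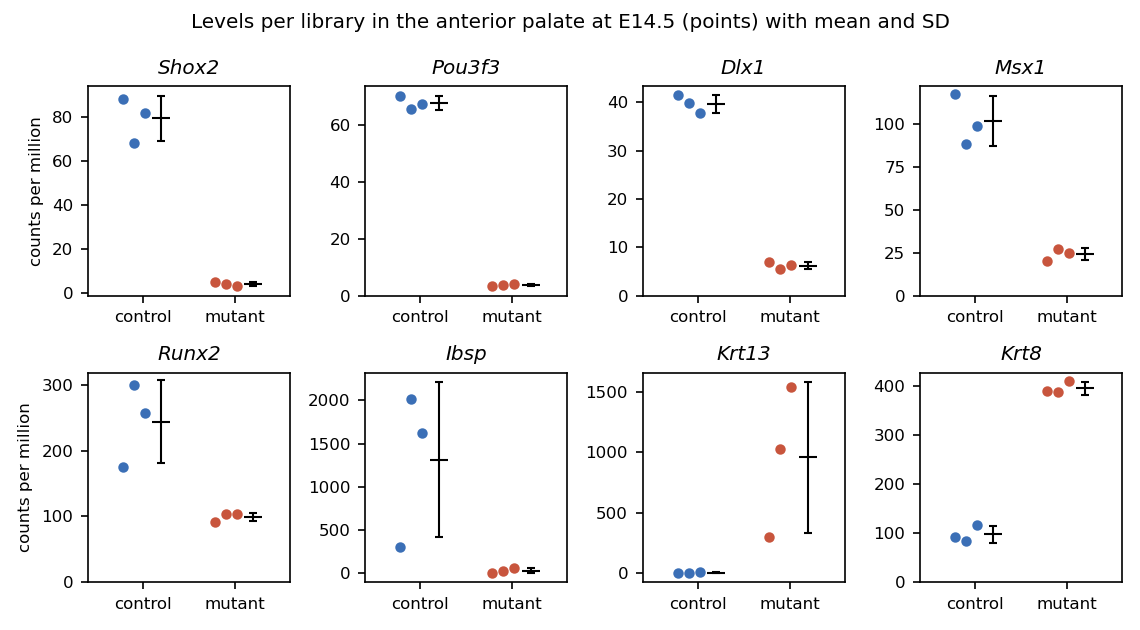
Levels in CPM of 8 genes in each of the 6 libraries, with points for libraries and bars for mean and SD (n = 3 per group). Shox2, Pou3f3, Dlx1, Msx1, Runx2 and Ibsp lie lower, and Krt13 and Krt8 higher, in every mutant than in every control. Pou3f3 was chosen after its values were seen.

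Osteoblast genes fell as a group in the mutant tissue. Of 31 measured members, 21 fell, 1 rose and 9 did not pass, and the counts adjusted over the list alone were the same. Runx2, the transcription factor that commits cells to bone, fell from 244 ± 63.4 to 99.3 ± 6.66 CPM (-1.3, SE 0.18, edgeR adjusted p = 0.00157). Pth1r, the parathyroid hormone receptor, fell (-1.54, SE 0.23), as did Phex (-2.99, SE 0.51) and Cthrc1 (-1.91, SE 0.33). Mepe, another osteocyte matrix gene, had 591 counts over the controls and 0 over the mutants, at least 97.3-fold lower. Collagen I and osteonectin transcripts did not pass: Col1a1 had a log2 fold change of 0.09 (SE 0.4), Col1a2 -0.2 (SE 0.31) and Sparc -0.15 (SE 0.32). The member that rose was Tnn, a tenascin (1.15, SE 0.35), and it was not called without control replicate 3 or with any 1 of the mutants left out. The median log2 fold change of the list was -1.54 (camera adjusted p = 0.000706, adjusted p = 0.551 with an estimated correlation, fry adjusted p = 0.0558). With the Y-linked covariate the median was -0.95, and 7 of the 22 called members stayed called in the same direction. The controls differed, with a mean level of 5.07 log2 CPM over the list in replicate 1 and 6.61 and 6.54 in replicates 2 and 3. Without replicate 1 of both groups, chosen after the data were seen, 26 members were called lower and 1 higher.

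Osteoclast genes fell alongside, with 6 of 10 members lower and none higher, and the same counts adjusted over the list alone. Mmp9, a matrix protease of osteoclasts, fell from 97.7 ± 20.6 to 13.3 ± 4.44 CPM (-2.88, SE 0.28), and Atp6v0d2, a subunit of their proton pump, fell as well (-4.56, SE 0.55). The list median was -1.72 (camera adjusted p = 0.0263, adjusted p = 0.551 with an estimated correlation), and the list was not called without mutant replicate 1 (adjusted p = 0.06) or with a filter of at least 1 CPM in 3 libraries (adjusted p = 0.0535). Of 21 chondrocyte genes, 5 were lower and 16 did not pass, and 2 were lower adjusted over the list alone. Col2a1, the main cartilage collagen, fell from 173 ± 48.8 to 52.9 ± 4.52 CPM (-1.71, SE 0.2). Col11a2 fell by 3.43 on the log2 scale (SE 0.64). The chondrocyte list was not called (camera adjusted p = 0.168). Its count of lower members was 2 without control replicate 2 or mutant replicate 1, and 3 without control replicate 3 or mutant replicate 2.

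Transcription factors of craniofacial mesenchyme changed in both directions. Of 35 members, 13 fell, 6 rose and 16 did not pass, with 16 lower and 6 higher adjusted over the list alone. Under the uncentred GC and length correction 17 fell and 3 rose, and with the correction centred 13 fell and 7 rose. Dlx1 fell from 39.7 ± 1.85 to 6.27 ± 0.729 CPM (-2.66, SE 0.12, edgeR adjusted p = 0.000108) and Dlx2, its neighbour in a homeobox gene pair, fell too (-2.32, SE 0.12). Tfap2b, a neural crest factor (-2.69, SE 0.16), and Lhx6 (-1.77, SE 0.13) were also lower. The list median was -0.44 (camera adjusted p = 0.0263, adjusted p = 0.551 with an estimated correlation), and the list was not called without control replicate 1 (adjusted p = 0.0791) or without replicate 1 of both groups (adjusted p = 0.0655). Among 10 genes of the anterior palate, 4 fell, 1 rose and 5 did not pass, the same adjusted over the list alone. The number that fell was 2 with library size only and 6 under the uncentred GC and length correction. Msx1, a homeobox gene needed for palate closure, fell from 117, 88.3 and 98.6 CPM to 20.5, 27.2 and 24.9 CPM (-2.07, SE 0.14), while Alx1 rose by 0.65 (SE 0.12). Bmp4 had a log2 fold change of -0.2 (SE 0.19) and did not pass. The list was not called (camera adjusted p = 0.202), and 2 members were lower without mutant replicate 1 or 3, with 2 higher without mutant replicate 1. Of the 4 posterior palate genes, Barx1 fell by 1.33 on the log2 scale (SE 0.13) and the other 3 did not pass, the same adjusted over the list alone (camera adjusted p = 0.614). Without control replicate 1, 1 posterior gene was called higher.

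Signalling genes moved in both directions, and with all 6 libraries no signalling list was called by camera. Of 38 BMP and activin genes, 10 fell and 5 rose (camera adjusted p = 0.202). Bmper, a secreted BMP modulator, fell by 1.85 on the log2 scale (SE 0.12), and Bmp3 rose by 1.07 (SE 0.12). The number that rose was 3 without mutant replicate 2. Of 51 WNT genes, 13 rose and 9 fell (camera adjusted p = 0.828). Frzb, a secreted WNT antagonist, fell from 285 ± 16.6 to 66 ± 8.14 CPM (-2.11, SE 0.1), and Dkk2 rose by 1.21 (SE 0.08). Of 18 hedgehog genes, 7 fell and 2 rose (camera adjusted p = 0.168), among them Foxf1 (-0.94, SE 0.1) and Gli1 (-0.86, SE 0.14), both targets of the pathway. Without control replicate 3 or mutant replicate 2, 1 hedgehog gene rose and 5 fell. Of 23 FGF genes, 7 fell and 2 rose (camera adjusted p = 0.145). Etv4, a transcriptional target of FGF receptors, fell from 41.9 ± 18.3 to 10.2 ± 0.707 CPM (-2.03, SE 0.29). Fewer FGF genes fell without mutant replicate 1 (3) or mutant replicate 2 (4). Of the FGF genes 1 rose without mutant replicate 3. Without control replicate 2 the FGF list was called (camera adjusted p = 0.0339), with 9 genes lower and 1 higher. Of 16 retinoic acid genes, 7 fell and 2 rose (camera adjusted p = 0.144). Aldh1a2, an enzyme of retinoic acid synthesis, fell from 148 ± 54 to 21.9 ± 7.84 CPM (-2.75, SE 0.35), and Cyp26c1, which breaks retinoic acid down, fell too (-2.41, SE 0.28). Of 16 Notch genes, 7 rose and 1 fell (camera adjusted p = 0.168). Notch1 rose from 92.4 ± 11.9 to 232 ± 4.69 CPM (1.33, SE 0.1), and Hey1, a target of Notch, was the member that fell (-0.72, SE 0.14). In these 6 lists the counts adjusted over the list alone were the same. The uncentred GC and length correction, which lowered the median of all genes, changed the splits to 12 higher and 20 lower for WNT, 4 and 18 for BMP and activin, 1 and 12 for hedgehog, 1 and 13 for FGF, and 4 and 1 for Notch, whose median went from 0.25 to -0.05. With the correction centred they were 14 and 10, 5 and 9, 2 and 5, 3 and 6, and 6 and 1.

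Epithelial genes rose as a group. Of 25 measured members, 23 rose and none fell, also adjusted over the list alone. Krt8, a keratin of simple epithelium, rose from 97.5 ± 16.8 to 395 ± 13.4 CPM (2.02, SE 0.12, edgeR adjusted p = 0.000189). Pkp1, a desmosome protein, rose by 2.75 (SE 0.21), Krt19 by 2.45 (SE 0.18) and Krt15 by 2.49 (SE 0.23). The list median was 1.6 (camera adjusted p = 7.6e-08, adjusted p = 0.551 with an estimated correlation). Of 12 nasal and olfactory genes, 5 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.2). Six3 rose by 2.41 (SE 0.18) and Stoml3, a gene of olfactory cilia, by 4.74 (SE 0.57). The 2 that fell were Dlx5 (-1.54, SE 0.33) and Ebf2 (-1.5, SE 0.49), and 1 fell without control replicate 1 or 2 or mutant replicate 3. Macrophage genes rose too, 15 of 16 with none lower, the same adjusted over the list alone. Cx3cr1, a chemokine receptor, rose from 11.6 ± 1.63 to 37.8 ± 4.82 CPM (1.7, SE 0.15), and the lysozyme gene Lyz2 by 2.89 (SE 0.35). The list median was 1.66 (camera adjusted p = 5.02e-06, adjusted p = 0.551 with an estimated correlation). Without replicate 1 of both groups 23 epithelial and 15 macrophage genes were called higher.

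Genes of tooth germ epithelium, skeletal muscle and red blood cells fell. Of 9 tooth germ genes, 5 fell and none rose, the same adjusted over the list alone (median -1.54, camera adjusted p = 0.00875, adjusted p = 0.551 with an estimated correlation). Fgf4, like Fgf3 a factor of the tooth signalling centre, had 504 counts over the controls and 0 over the mutants, at least 83-fold lower, and Lef1 fell by 1.6 on the log2 scale (SE 0.16). Of 16 skeletal muscle genes, 12 fell and none rose, and 14 fell adjusted over the list alone (median -2.69, camera adjusted p = 0.00239, adjusted p = 0.551 with an estimated correlation). By fry the muscle list was not called (adjusted p = 0.0558). The controls differed, with a mean level over the list of 2.39, -0.32 and 1.07 log2 CPM in replicates 1, 2 and 3, and the median was -1.55 without control replicate 1. Tnni1, a slow muscle troponin, fell from 3.24 ± 1.93 to 0.276 ± 0.0209 CPM (-3.54, SE 0.49). Without mutant replicate 1, 2 or 3 the muscle count was 7, 3 and 4, and without replicate 1 of both groups it was 8. The muscle list was not called with the 1 CPM filter (adjusted p = 0.0595). Of 8 genes of red blood cells, 5 fell and none rose, the same adjusted over the list alone (median -1.52, camera adjusted p = 0.014, adjusted p = 0.551 with an estimated correlation). That list was not called without replicate 1 of both groups (adjusted p = 0.0539) or with the 1 CPM filter (adjusted p = 0.0595). The embryonic globins Hbb-bh1 (-4.87, SE 1.06) and Hba-x (-2.54, SE 0.46) fell with Hbb-y, whereas the adult beta globin Beta-s had a log2 fold change of -0.14 (SE 0.28).

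Genes of DNA replication and mitosis were lower by small amounts. Of 33 members, 23 fell, none rose and 10 did not pass, with 27 lower adjusted over the list alone (median -0.5, camera adjusted p = 7.6e-08, adjusted p = 0.551 with an estimated correlation). Ccne1, the cyclin of entry into DNA synthesis, fell from 56.6 ± 1.98 to 34.3 ± 1.2 CPM (-0.73, SE 0.07). Bub1b, of the mitotic checkpoint, fell by 0.74 on the log2 scale (SE 0.07). Mki67 had a log2 fold change of -0.17 (SE 0.1) and did not pass. Of 20 p53 and apoptosis genes, 7 rose and 5 fell, with 8 and 5 adjusted over the list alone (camera adjusted p = 0.455), and the median of 0.13 turned to -0.12 under the uncentred GC and length correction. Perp, also an epithelial gene, rose by 2.33 (SE 0.22), and Bax fell (-0.65, SE 0.09). Of 17 stress and immediate early genes, 7 rose and none fell, the same adjusted over the list alone (camera adjusted p = 0.0263, adjusted p = 0.551 with an estimated correlation). The heat shock genes Hspa1b (1.69, SE 0.16) and Hspa1a (1.85, SE 0.2) were among them. That list was not called without control replicate 2 (adjusted p = 0.0881), mutant replicate 1 (adjusted p = 0.0801) or replicate 1 of both groups (adjusted p = 0.111), and its median of 0.26 was 0.55 without control replicate 3 and turned to -0.05 under the uncentred GC and length correction.

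The remaining lists were not called by camera. Of 27 hyaluronan and matrix genes, 9 rose and 5 fell, with 10 and 5 adjusted over the list alone (camera adjusted p = 0.316). The split depended on scaling, with 6 higher and 7 lower under the uncentred GC and length correction (median -0.1 in place of 0.19), 8 and 5 with it centred, and 13 and 5 with library size only. Has2, the main hyaluronan synthase of embryonic mesenchyme, fell from 97.9 ± 12.3 to 52.5 ± 4.36 CPM (-0.9, SE 0.11), and Dcn, decorin, rose by 0.71 (SE 0.12). Of 9 tendon genes, 3 fell and 1 rose, with 5 and 1 adjusted over the list alone (camera adjusted p = 0.263). Egr2 fell by 2.45 on the log2 scale (SE 0.5). No tendon gene rose without control replicate 2 or with any 1 of the mutants left out, and 2 fell without mutant replicate 2. Of 17 nerve and glia genes, 6 fell and 3 rose, with 7 and 3 adjusted over the list alone (camera adjusted p = 0.289). Tubb3, a neuronal tubulin, fell from 38.9 ± 16.3 to 5.09 ± 0.39 CPM (-2.93, SE 0.3), while the glial receptor gene Erbb3 rose by 1.32 (SE 0.27). Of 13 genes of the sinoatrial program, 2 rose and 2 fell, with 2 and 1 adjusted over the list alone (camera adjusted p = 0.289). The number that fell was 1 without control replicate 1 or 2 or mutant replicate 2 or 3. With library size only 4 sinoatrial genes rose and 1 fell, and under the uncentred GC and length correction 2 rose and 3 fell. Isl1 rose from 6.71 ± 1.9 to 22.3 ± 1.43 CPM (1.74, SE 0.21). Of 14 endothelial genes 2 rose (camera adjusted p = 0.168), among them Vwf (1.16, SE 0.19). The number called was 5 without mutant replicate 1 and 1 without mutant replicate 2 or 3. With the replicate number as a block 4 endothelial genes rose. Under the uncentred GC and length correction 1 rose and 1 fell. Of 11 mural cell genes 2 rose (camera adjusted p = 0.145), with 4 called without control replicate 2, and Rgs5 rose by 1.06 (SE 0.15). With DESeq2 size factors, upper-quartile normalization or library size only, 4 mural cell genes rose. Of 4 measured Hox genes, Hoxd8 (1.25, SE 0.28) and Hoxd9 (1.25, SE 0.37) rose, and 1 rose without control replicate 2 or 3 or mutant replicate 3 (camera adjusted p = 0.145). Without mutant replicate 3, when 7 Hox genes were measured, 1 was called lower. Hoxd9 was also not called without mutant replicate 2 (adjusted p = 0.0993). In the endothelial, mural and Hox lists the counts adjusted over the list alone were the same.

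**Figure D2:**
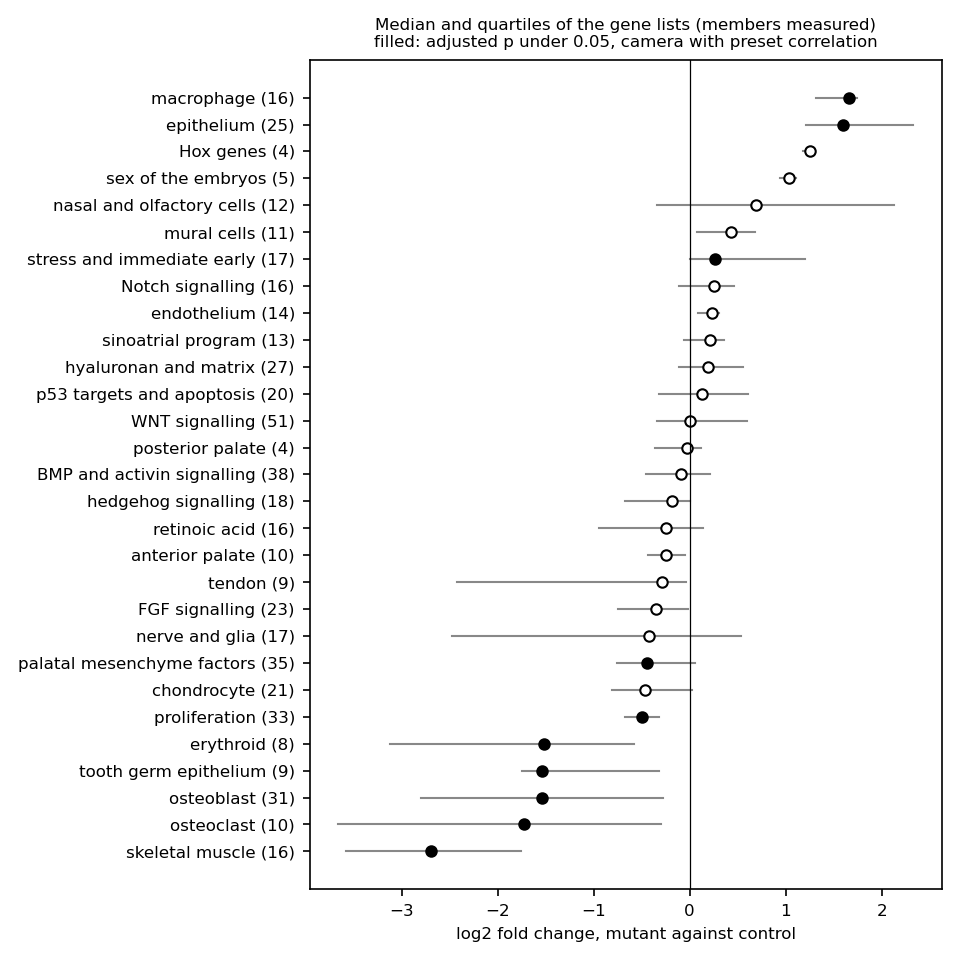
Median log2 fold change of mutant against control for the 29 gene lists, with lines from the lower to the upper quartile of members and the number of measured members in brackets. Filled points mark the 10 lists called by camera with the preset correlation, from skeletal muscle at -2.69 to macrophage at 1.66, and none was called with an estimated correlation.

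The sex-linked transcripts differed between the groups. Xist, expressed from the inactive X chromosome of females, was present in every control library, at 589 ± 319 CPM, and at 0.295 ± 0.0363 CPM in the mutants (-10.96, SE 0.68, edgeR adjusted p = 0.000189). Mean CPM of the 4 Y-linked genes was 47.9, 9.05 and 21.9 in control replicates 1, 2 and 3 and 49.8, 60.9 and 52 in the mutants. Over both groups the Y-linked genes did not pass, with log2 fold changes from 0.94 (Ddx3y, SE 0.55) to 1.23 (Uty, SE 0.53). Without control replicate 1 all 4 were called higher. The list was not called (camera adjusted p = 0.685), and Xist was its only called member, also adjusted over the list alone. The genotype groups thus differed in sex-linked transcripts beside every gene group described.

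**Figure D3:**
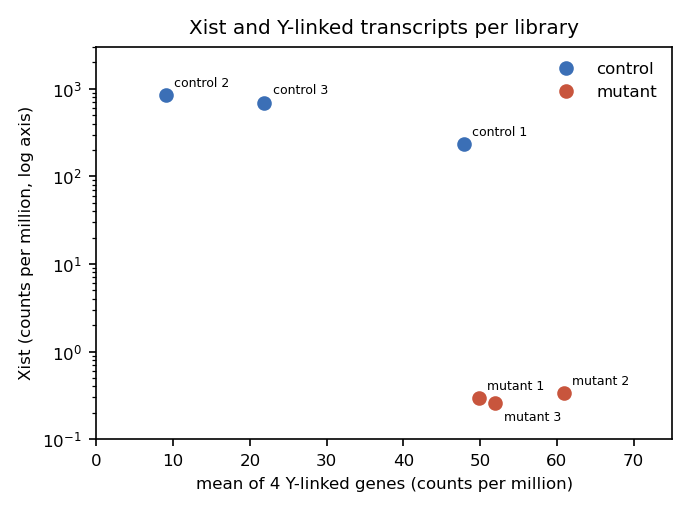
Xist in CPM on a log axis against the mean of 4 Y-linked genes in CPM, with 1 point per library. The controls hold both kinds of transcript, with Xist between 232 and 843, and the mutants lie at 0.261 to 0.333 for Xist with Y-linked means from 49.8 to 60.9.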

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

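The Y-linked covariate, the GC and length corrections, thinning, halved counts, X and Y genes left out and both replicate 1 libraries left out were chosen after seeing the data. Shox2 kept its direction and its call under all 22 other settings, with log2 fold changes from -4.53 to -4.07 and adjusted p from 7.73e-101 to 0.00198. Among the named genes and the 29 lists, none changed sign with a call. For other genes signs were compared only where both settings gave a call, and none differed. Of 118 named genes tested, 94 kept their call or lack of one under each setting that tested them, 11 of the 118 were not tested under every one of the 22 settings because a filter or the genes left out removed them, and the Y-linked covariate (15 genes) and limma-voom (10 genes) ended the most calls. Against a 1.5-fold threshold 2472 genes were called, 1967 higher and 505 lower, fewer by construction. With the Y-linked covariate 4874 were called, 2635 higher and 2239 lower. That covariate goes with genotype in part and costs a degree of freedom, and the cause of the lower count was not tested. The uncentred GC and length correction gave 6243 lower genes. It also shifted the median of all genes, and the centred form gave 3613, so the shift in scaling accounts for the difference. Leaving out 1 library at a time gave 5780 to 7659 called genes, 3170 to 3998 higher and 2610 to 3661 lower, with Shox2 between -4.45 and -4.07 and 8 to 10 lists called. Of the 29 lists, 10 were called by camera with the preset correlation, 0 with an estimated correlation and 17 by fry, which asks whether a list moves and not whether it moves more than other genes. The osteoblast and skeletal muscle lists were not called by fry (adjusted p = 0.0558 each). Fry called 9 lists that camera did not, with fry adjusted p from 0.0097 to 0.0462. They were BMP and activin, retinoic acid, Notch, anterior palate, sinoatrial program, p53 and apoptosis, tendon, nasal and olfactory, and Hox genes. With an estimated correlation no list had an unadjusted p under 0.05. With the replicate number as a block 7022 genes were called, 3720 higher and 3302 lower, with Shox2 at -4.26 and 10 lists called. Whether the numbers pair the libraries was not settled. Deviations of same-numbered libraries correlated weakly, at 0.081, 0.082 and 0.02, and each group had only 3 libraries. Every library correlated best with its own number except control replicate 3, which was closer to mutant replicate 2 (0.048). The planned covariate of inferred sex was not run, because every control library held both Xist and Y-linked reads. Mitochondrial transcripts were not among the genes of the files, so only globin genes were left out. Thinning all libraries to the smallest total left 7515 called genes, 7368 of them shared with the full counts.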

Other observations

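Tests of epithelial share, of unscaled counts, of embryonic globins, of other tissue in the controls, of age for the osteoblast genes, of lung as the whole cause, of sexes within the controls and of sex for the osteoblast genes, the epithelial genes and Shox2 taken apart were chosen after the result was seen. The 5 lists used here beside the fixed ones, and the genes named outside the rule, were also chosen then. Genes of motile cilia rose. Of 23 dynein, radial spoke and tektin genes of the motile cilium families, 21 rose and none fell, with a median log2 fold change of 3.69 (camera adjusted p = 1.18e-09, adjusted p = 0.277 with an estimated correlation). Dnahc5, an outer arm dynein, rose from 3.2 ± 2.58 to 165 ± 45.9 CPM and Dnahc9 from 1.25 ± 0.632 to 73 ± 22.9 CPM. Foxj1, the master factor of motile cilia, rose by 2.26 (SE 0.5), from 63.5 ± 42.2 to 304 ± 8.2 CPM. The 3 measured small proline-rich genes, of cornifying epithelium, rose (median 6.29, camera adjusted p = 0.0534), with Sprr1a at 9.56, 61.9 and 119 CPM in mutant replicates 1, 2 and 3.

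Of 81 ribosomal protein genes, 59 fell and none rose, with a median of -0.55 (camera adjusted p = 4.78e-14, adjusted p = 0.277 with an estimated correlation). Pou3f3, a POU factor of craniofacial mesenchyme, fell from 67.8 ± 2.4 to 3.96 ± 0.316 CPM (-4.1, SE 0.1, edgeR adjusted p = 8.48e-06). Tbx15 fell from 27.3 ± 6.45 to 2.45 ± 0.399 CPM (-3.48, SE 0.22), and Hmga2 fell from 269 ± 41.5 to 47.7 ± 0.723 CPM (-2.49, SE 0.11). Of 7 embryonic age genes 3 fell and 2 rose (camera adjusted p = 0.121). None rose without control replicate 3 or mutant replicate 2, 1 rose without control replicate 1 or mutant replicate 1 or 3, and 5 fell without mutant replicate 1. Of 7 lung genes beside Sftpc, 3 passed the filter and rose (camera adjusted p = 0.0169, adjusted p = 0.277 with an estimated correlation), with Nkx2-1 at 0.282 CPM in the mutants. Nkx2-1, with 0, 0 and 2 counts in the controls, passed the filter only through the mutants. The list was also chosen after the data were seen, so its test is no independent evidence of a rise of lung genes. The other 4 were too low to be tested: Sftpb went from 0.0353 ± 0.0275 to 0.0633 ± 0.11 CPM, Lamp3 from 0.0848 ± 0.0418 to 0.0751 ± 0.0973 CPM and Scgb3a2 from 0 to 0.611 ± 0.448 CPM, and Sftpa1 had 0 counts in the mutants. In mutant replicate 1 Gapdh was at 13.3 CPM, against 77 and 86.3 CPM in mutant replicates 2 and 3. Lars2 was at 1390, 1140 and 727 CPM in control replicates 1, 2 and 3 and at 78.2, 371 and 189 CPM in the mutants.

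The rise of ciliated and stratified epithelium genes was weighed against 4 explanations beside the genotype. Depth as the whole cause is argued against, since 75% of the called motile cilium and epithelial genes (17 of 21 and 16 of 23) had more unscaled counts in every mutant than in every control, although the mutants were shallower. Thinning, after which 100% of the called motile cilium genes were still called higher, decides nothing here, because the mutants were already the smallest libraries. A larger share of epithelium remains open: the cilium median exceeded the epithelial median by 2.09, past the bound of 1, but the quartiles overlapped. Of the 7 lung genes beside Sftpc, 5, Nkx2-1 among them, lay under 1 CPM in the mutants, where Dnahc5 was at 165 CPM. RNA of lung as the whole cause is argued against only if lung of this stage holds these genes, which was not analysed here. Whether the mutants held a small amount of lung RNA cannot be told apart from a rise of these genes in the palate, since 2 lung genes beside Sftpc (Sftpd at 1.72 and Napsa at 4.57 CPM) met the bound, between the limits set for and against it. A later embryonic age may contribute: the embryonic globins lay -4.73 from the adult globin in median log2 fold change. The embryonic age genes, a list added after the data were seen, had a median of -0.51, just past the bound of -0.5 set beforehand. That median was read as undecided since members went both ways, a condition added after the value was seen. With 1 library left out this median lay between -0.66 (without mutant replicate 1) and -0.3 (without mutant replicate 2), on both sides of that bound, and the 2 that rose were Lin28a, at 0.301 CPM in the mutants, and Dlk1 (adjusted p = 0.0477), so neither the median nor the rises were stable.

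The fall of osteoblast genes was weighed against 3 explanations beside the loss of Shox2. Different counting of mutant replicate 1 is argued against, since 90.5% of the members called lower stayed so without it. If an older palate holds more bone, a later age of the mutant tissue would raise the osteoblast genes. The list median was -1.54 (quartiles -2.8 and -0.28), which argues against a later age as the whole cause on that premise. How bone genes move with age was not analysed here. Other tissue in the control dissections may contribute and stays open, since tooth germ and muscle genes were lower too (the higher of the medians was -1.54). Against it, Shh, a tooth germ gene at 23.2 CPM in the controls and 18.6 CPM in the mutants, did not pass. However, oral epithelium also holds Shh, and 4 of the 11 tooth germ genes are in another list. Whether other tissue bears on the falls among anterior palate, posterior palate and craniofacial mesenchyme genes was not tested.

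The fall of Xist was weighed with respect to the sexes of the embryos. All 3 control libraries held Xist above 10 CPM and 4 Y-linked genes above 1 CPM, moving in opposite directions, so both sexes in each control library is a candidate explanation, as in pools. With the Y-linked covariate Shox2 stayed lower (-4.45, edgeR adjusted p = 0.00151), which argues against the Y-linked level as the whole cause of its fall. The same holds for the epithelial genes, of which 87% of the called members stayed called in the same direction, with a list median of 1.25 (quartiles 0.91 and 1.92) against 1.6 (1.21 and 2.33) without the covariate. For the osteoblast genes sex composition may contribute and stays open: 31.8% of the called members stayed called, and the median went from -1.54 (quartiles -2.8 and -0.28) to -0.95 (-1.36 and 0.15). Control replicate 1 had both the lowest osteoblast level and the highest Y-linked level of the controls, and the covariate goes with genotype in part and costs a degree of freedom. Over both lists together 60% stayed called, between the bounds of 50% and 80% set beforehand. Xist lay at 232 to 843 CPM in the controls and at 0.261 to 0.333 CPM in the mutants, so it separated the groups completely. Control replicate 1 held Xist beside a Y-linked mean of 47.9 CPM, near the 49.8 CPM of mutant replicate 1. The covariate therefore cannot stand for the share of female tissue. For both lists, sex composition cannot be told apart from genotype. The mutants lack a wild-type Shox2 allele by genotype. Across controls with Xist from 232 to 843 CPM, Shox2 stayed between 68.2 and 88.2 CPM, which argues against sex composition as the whole cause of its fall.

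Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many called genes, with 7606 against at most 0 in the others. With 10 splits no share under 0.05 can be reached. Each of the other splits mixed the genotypes within both groups, so the genotype difference entered the spread within groups. Their 0 calls therefore do not measure what chance alone would give.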
